A study of Mus musculus with 6 samples.

How the data were processed

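Single-cell T cell receptor (TCR) sequencing was available for 6 mouse libraries, each the only library of its group. The reads were processed by the authors with Cell Ranger 6.1.2 on the mm10 genome build, per the submitters' processing notes. The assay was 10x Genomics droplet sequencing with V(D)J enrichment, which amplifies rearranged receptor transcripts and tags each molecule with a unique molecular identifier (UMI). Tumours were cut up and digested with collagenase and DNase for 30 minutes, passed through a 70 µm strainer and kept for cell sorting, per the labels' protocols. The gate of that sort is not given in the sources used here.

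The contig tables hold whole counts of reads and UMIs for every assembled contig, per the file headers, beside its V, D, J and C calls, its CDR3 sequence and the authors' Cell Ranger flags for called cells, high confidence, full length and productivity. The consensus tables hold the same counts per deposited clonotype. The metrics tables give percent values for read quality and mapping and, per the file headers, totals of reads and cells. Median UMIs per cell and a paired diversity score were also deposited by the authors in those metrics tables. No value was normalized by the authors between libraries, as far as the file headers show.

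A paired cell was a called cell with at least 1 productive, full-length, high-confidence TRA contig and 1 such TRB contig. Its clonotype was the V gene, J gene and CDR3 nucleotide sequence of the TRA and TRB contigs with most UMIs, with ties broken by reads and then by CDR3 in alphabetical order. A clonotype was called expanded when 2 or more paired cells carried it. Because larger samples hold more repeats, the expected number of clonotypes and the expected expanded share were also computed for 51 paired cells, the size of the smallest library, by the exact formula for draws without replacement. Segment usage was counted with each clonotype taken once. A segment was called higher or lower where the intervals of 2 libraries did not overlap.

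With 1 library per group no test between conditions was possible. No p-value is given, and every difference has no replicate check. Shares carry 95% exact Clopper-Pearson intervals from SciPy 1.17.1, which cover counting error only, and a count of 0 carries the upper limit set by 3 counts. For shares of cells in expanded or large clonotypes these intervals treat cells as independent, although cells of 1 clonotype are counted together. Computations used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots used matplotlib 3.10.9.

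The comparisons, definitions and alternatives were fixed before the data were examined. For each of 8 comparisons, the segments to name were those with the largest difference among segments used by at least 5% of clonotypes in either library, up to 8 TRBV, 8 TRAV, 4 TRBJ and 4 TRAJ. The clonotypes to name were the 3 largest of each library with at least 3 cells, and those found in 2 or more libraries with at least 3 cells in all. Groups of segments were the TRBV families, the TRBJ clusters, the TRAV subgroups with their duplicated D and N copies merged, and the proximal and distal parts of the TRAJ cluster. Invariant natural killer T (NKT) cells were TRAV11 or TRAV11D with TRAJ18 and a partner from TRBV1, TRBV13 or TRBV29. Mucosal-associated invariant T (MAIT) cells were TRAV1 with TRAJ33 and TRBV13 or TRBV19. TRG, TRD and immunoglobulin contigs marked gamma-delta T cells and B cells, and 2 or more TRB contigs marked a possible droplet with 2 T cells. Such cells were kept in the main setting.

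Alternatives were the TRB chain alone, amino acid CDR3s of both chains, the deposited clonotypes, single-chain cells included, 2 or more UMIs on both chains, exactly 1 TRA and 1 TRB, barcodes called in 1 library only, and productive contigs without high confidence included. Expansion was also computed with clonotypes of 3 or more cells, usage and CDR3 length by cells, and invariant receptors by the TRA chain alone. Nucleotide CDR3s without V and J were added after seeing the data, and so were the 1000 draws that deal the NooT and NeOT clonotypes out at random.

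The functions were tested on simulated data. Of 40 identical and 40 near-identical receptors planted in the DC and NeOT libraries after random re-pairing of chains, 40 and 40 were recovered. The planted receptors met the search definition by construction, so their recovery checks the code only. It measures neither sensitivity nor false matches in the real data. For DC against NS, the intervals separated for 0.25% of simulated TRBV segments with equal shares, for 54.5% with a 3-fold difference and for 97.9% with a 5-fold difference. For T against NS these values were 0%, 31.0% and 82.8%, and for NooT against NeOT they were 1%, 99.1% and 100%. Only TRBV segments used by at least 5% of clonotypes in the second library were simulated, with the share raised in the first. Lower shares in the first library, rarer segments and TRAV, TRBJ and TRAJ segments were not simulated.

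Gene positions come from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names. Of 166 segment names in the files, 165 matched a symbol when case was ignored. The exception was the composite entry TRBV12-2+TRBV13-2, which the files use as 1 V gene. V genes with near-identical copies (TRAV6 and TRAV6D, for example) can be swapped by the caller and are uncertain at the level of the copy.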

Results

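The T cell receptors of cells from LL/2 tumours, a mouse Lewis lung carcinoma line, were sequenced after saline, vaccination or T cell transfer. The NS library came from tumour tissue after saline. DC came after treatment with dendritic cells, antigen-presenting cells grown from bone marrow for 8 days with 20 ng/ml GM-CSF. OCDC came after the OCDC vaccine, T after T cell transfer, and NeOT after OCDC together with neoantigen-reactive T cells. NooT was labelled as neoantigen-reactive T cells treated with OCDC. Its tissue label also reads tumour, so whether it holds cells before or after transfer is not settled by the labels. The other 5 are called tumour libraries below, as a name only. Each group had 1 library, so no difference between conditions has a replicate check. The number of mice pooled in a library and the tumour site are not settled by the labels. The expanded shares, diversity and receptor sharing below can therefore describe 1 mouse or several.

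The libraries had similar numbers of read pairs but very different numbers of T cells. Read pairs ranged from 33021850 in NeOT to 44060506 in NooT. Called cells numbered 58 in NS, 267 in DC, 106 in OCDC, 80 in T, 217 in NeOT and 7056 in NooT. Reads mapped to V(D)J genes made up 83.9% in NooT and between 7.8% in NS and 19.3% in NeOT among the tumour libraries. These cell numbers measure what was loaded and sorted and give no T cell density of the tumours.

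Most called cells had both receptor chains. Paired TRA and TRB contigs were found in 51 NS cells (87.9%, lower 95% exact limit 76.7%), 225 DC cells (84.3%), 93 OCDC cells (87.7%), 65 cells of the T library (81.3%) and 188 NeOT cells (86.6%). NooT had 4896 paired cells, and its share of 69.4% (68.3% to 70.5%) was lower, with an interval below those of the 5 tumour libraries. Cells with 2 or more productive TRB contigs, a sign of 2 T cells in 1 droplet, made up 6.83% of NooT cells and between 0.943% in OCDC and 2.62% in DC among tumour libraries. Paired cells had a median of 5 or 6 TRA UMIs in every library, and 8 to 12 TRB UMIs.

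Clonal expansion was compared first between the vaccine groups and saline. In DC 26.2% of paired cells (20.6% to 32.5%, 59 of 225 cells) belonged to clonotypes of 2 or more cells. In NS the share was 5.88% (1.23% to 16.2%, 3 of 51 cells), so DC was higher and the intervals did not overlap. OCDC, at 6.45% (2.40% to 13.5%, 6 of 93 cells), was close to NS and lower than DC, with intervals apart from those of DC. DC had 20 expanded clonotypes, OCDC had 2 and NS had 1. The intervals of expanded shares, here and below, count cells as independent draws. Cells of 1 clonotype are counted as expanded together, so these intervals do not measure the full sampling error. Whether 2 of them overlap is a description only. At 51 paired cells the expected expanded share was 12.0% for DC, 5.13% for OCDC and 5.88% for NS. The DC value at 51 cells lay inside the interval of NS, which has 51 cells. It also lay inside that of OCDC, which comes from all 93 OCDC cells and is no comparison at equal numbers.

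The transfer groups also held expanded T cells. In the T library 44.6% of paired cells (32.3% to 57.5%, 29 of 65 cells) belonged to 13 expanded clonotypes, higher than NS with intervals apart. At 51 cells the expected share of the T library was still 37.0%. NeOT had 24.5% of cells (18.5% to 31.3%, 46 of 188) in 20 expanded clonotypes, higher than NS and OCDC and lower than the T library, with intervals apart each time. At 51 cells its expected share was 8.68%, inside the interval of NS. Of the 13 expanded clonotypes of the T library, 11 had exactly 2 cells. So had 16 of 20 in NeOT and 13 of 20 in DC. Clonotypes of 3 or more cells held 10.8% of T library cells against 14.7% in DC. The 10 largest clonotypes of the T library held 35.4% of its 65 paired cells (23.9% to 48.2%). The 10 largest held 17.3% of 225 cells in DC and 13.8% of 188 in NeOT, and this share also depends on the number of cells sampled.

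**Figure D1:**
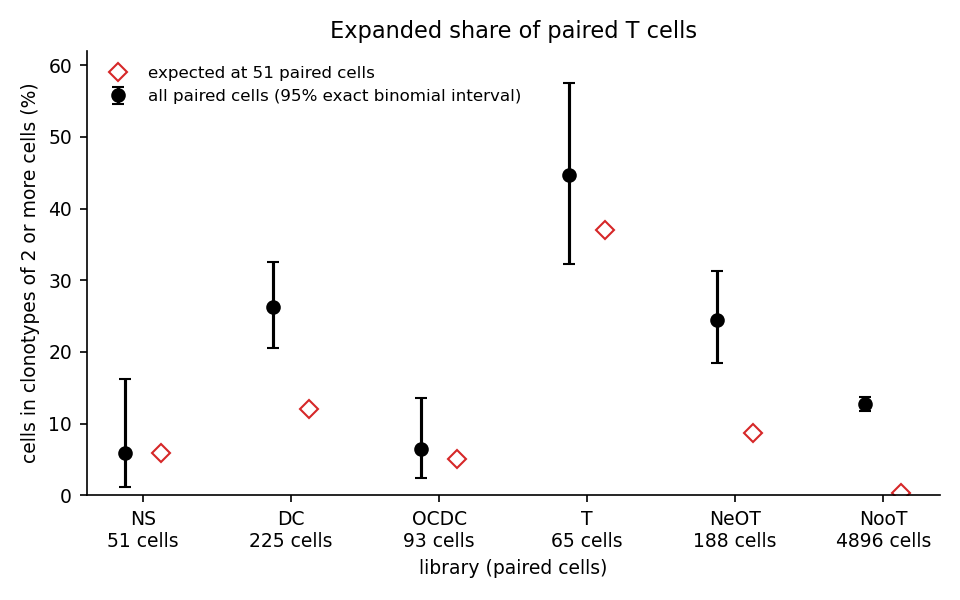
Share of paired cells in clonotypes of 2 or more cells (%, y axis) for the 6 libraries (x axis, with their paired cells). Black points show all paired cells with 95% exact binomial intervals, and open diamonds show the share expected at 51 paired cells. The T library was highest by both measures, at 44.6% and 37.0%, and NooT was at 12.7% and 0.318%.

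NooT, set against NeOT, was the most diverse library. Its 4896 paired cells held 4507 clonotypes, of which 233 were expanded with 12.7% of cells (11.8% to 13.7%). At 51 cells its expected expanded share was 0.318% against 8.68% in NeOT. Its largest clonotype held 12 cells, or 0.245% (0.127% to 0.428%), and its 10 largest held 1.74%. The 10 largest clonotypes of NeOT held 13.8% (9.24% to 19.6%). These shares depend on the number of cells, 188 in NeOT and 4896 in NooT, so they are no comparison at equal numbers. In 51 sampled cells 50.9 distinct clonotypes were expected in NooT, 49.5 in OCDC, 49 in NS, 48.7 in NeOT, 47.4 in DC and 40.8 in the T library. The Gini-Simpson index, the chance that 2 cells drawn at random differ in clonotype, was 0.990 in the T library and at least 0.996 in the others.

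**Figure D2:**
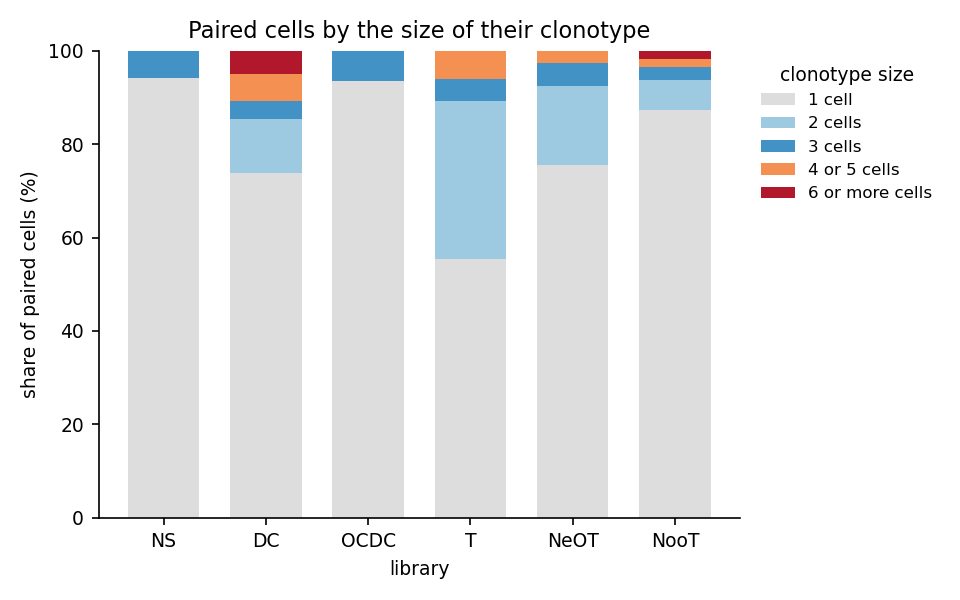
Stacked bars give the share of paired cells (%, y axis) by the size of their clonotype for each library (x axis). Cells in clonotypes of 2 cells made up 33.9% of the T library, 17.0% of NeOT and 11.6% of DC, and the largest clonotypes had 12 cells in NooT and 11 in DC.

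The largest clonotypes differed between libraries. The largest DC clonotype had 11 cells (4.89%, 2.47% to 8.58%) and paired TRAV7D-2/TRAJ7 with CDR3 CAAKDYSNNRLTL to TRBV5/TRBJ2-3 with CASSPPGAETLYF. The same TRB occurred in 4 further DC cells in which TRAV6D-5/TRAJ9 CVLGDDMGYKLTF had more UMIs. All 4 of those cells, and 7 of the 11, carried more than 1 TRA, so 15 cells shared this TRB. The other leading DC clonotype had 5 cells with TRAV16D-DV11/TRAJ45 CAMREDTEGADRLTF and TRBV20/TRBJ1-2 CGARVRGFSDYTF. In 4 more cells the same CDR3 residues were assigned to TRAV16, a near-identical copy, which makes 9 cells by CDR3 residues. The TRA CDR3 bases differed between the 5 and the 4 cells, so whether these 9 cells are 1 clone is not settled.

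In NeOT the leading clonotype had 5 cells (2.66%, lower limit 0.869%) with TRAV6-7-DV9/TRAJ48 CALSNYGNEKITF and TRBV3/TRBJ1-1 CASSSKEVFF. It was followed by TRAV4-4-DV10/TRAJ34 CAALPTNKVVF with TRBV1/TRBJ1-1 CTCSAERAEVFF and TRAV8D-2/TRAJ12 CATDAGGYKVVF with TRBV15/TRBJ1-5 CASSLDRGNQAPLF, each in 3 cells. The TRB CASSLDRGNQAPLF also occurred in 3 further NeOT cells, in which TRAV9D-3/TRAJ38 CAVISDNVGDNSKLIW had more UMIs. More than 1 TRA was carried by 2 of the first 3 cells and by all 3 of the others. In all, 6 cells shared this TRB, more than the 5 of the leading clonotype. The T library was led by TRAV10N/TRAJ27 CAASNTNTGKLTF with TRBV14/TRBJ1-3 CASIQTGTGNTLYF in 4 cells and by TRAV4D-4/TRAJ21 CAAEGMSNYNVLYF with TRBV30/TRBJ2-1 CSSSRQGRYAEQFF in 3 cells. The only expanded NS clonotype paired TRAV5-4/TRAJ57 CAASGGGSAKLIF with TRBV2/TRBJ2-7 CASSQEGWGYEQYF in 3 cells. OCDC had TRBV14/TRBJ2-7 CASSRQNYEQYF with TRAV12D-3/TRAJ28 and TRBV1/TRBJ2-5 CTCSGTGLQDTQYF with TRAV14-2/TRAJ47, each in 3 cells. Some of these rest on few UMIs. The median was 3 TRB UMIs for the NS clonotype, 2 for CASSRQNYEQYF in OCDC and 2 for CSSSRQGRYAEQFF in the T library. Over all paired cells it was 9 in NS, 8 in OCDC and 8 in the T library. NooT was led by TRAV13D-2/TRAJ30 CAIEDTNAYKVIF with TRBV26/TRBJ2-7 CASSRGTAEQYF in 12 cells, TRBV3/TRBJ1-5 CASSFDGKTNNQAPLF in 11 and TRBV26/TRBJ2-2 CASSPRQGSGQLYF in 10. None of these leading clonotypes was found in another library.

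Whether receptors of NooT were seen in tumours was asked by matching clonotypes exactly. Of the 15 pairs of libraries, 14 shared no clonotype. The exception was NooT with NeOT, which shared TRAV5-1/TRAJ6 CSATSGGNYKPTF with TRBV26/TRBJ2-7 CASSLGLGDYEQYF. It was found in 2 NooT cells and 1 NeOT cell, which is 0.532% of NeOT cells (0.0135% to 2.93%). No called barcode was present in both of these libraries. NooT clonotypes were found in 0 of 225 DC cells, 0 of 93 OCDC cells, 0 of 65 cells of the T library and 0 of 51 NS cells, which allows shares of up to 1.33%, 3.23%, 4.62% and 5.88%. By the TRB chain alone, NooT matched 1.45% of NeOT cells (3 of 207) and 1.18% of DC cells (3 of 255). It matched 2% of OCDC cells (2 of 100), 1.33% of cells of the T library (1 of 75) and 0 of 56 NS cells. NeOT therefore did not stand apart from DC and OCDC, whose labels name no neoantigen-reactive T cells.

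The NooT sample covered a small part of its pool, and this limits the search. Cells in clonotypes seen more than once made up 12.7% of NooT, which by Good-Turing counting estimates the share of the pool that its clonotypes represent. The next values hold only if NooT represents the cells given to the NeOT mice, which the labels do not settle. If every NeOT T cell had been drawn from that pool at the same clone frequencies, 23.9 of 188 cells would be expected to match, against 1 observed. The upper limit of 2.93% on the matched share still allows up to 23.05% of NeOT cells from that pool, at the same clone frequencies. This limit leaves out the error of the 12.7%.

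Segment usage was compared between vaccinated and saline tumours. TRBV16 was used by 14.3% of NS clonotypes (5.94% to 27.2%), 4.84% of DC clonotypes (2.24% to 8.99%) and 4.49% of OCDC clonotypes (1.24% to 11.1%). The composite entry TRBV12-2+TRBV13-2, whose CDR3s start with CASG in 96.4% of cases as those of TRBV13-2 do, was used by 20.2% of OCDC clonotypes (12.5% to 30.1%), 10.8% in DC and 14.3% in NS. TRBJ2-7 was used by 26.5% of NS clonotypes, 15.1% in DC and 12.4% in OCDC, and TRBJ2-5 by 4.08%, 14.0% and 14.6%. TRAV14-2 was used by 8.16% in NS against 0.538% in DC and 1.12% in OCDC. TRAV11, the V segment of the invariant NKT receptor, was used by 5.62% of OCDC clonotypes, 4.08% in NS and 1.08% of DC clonotypes. The intervals of every named segment overlapped, 21 for DC against NS, 22 for OCDC against NS and 19 for OCDC against DC. So did those of all 17 TRBV families of DC against NS, among which TRBV13 was used by 21.0% in DC, 36.0% in OCDC and 22.4% in NS. TRAV9 was used by 20.4% in NS (10.2% to 34.3%), 8.60% in DC and 5.62% in OCDC, and all 19 TRAV subgroups of DC against NS and all 16 of OCDC against NS overlapped. No difference in usage was detectable at this depth. The intervals of TRAV14-2 overlapped at 8.16% in NS and 0.538% in DC, so large differences are not excluded.

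For the transfer groups, usage was compared for the T library with NS and for NeOT with NS, OCDC and the T library. TRBV16 was used by 4.08% of clonotypes in the T library and 8.02% in NeOT, against 14.3% in NS. TRBV14 was used by 5.56% of NeOT clonotypes (2.57% to 10.3%) and 0 of 49 in NS, which allows up to 6.12%. TRBV31 was used by 8.16% in the T library, 8.02% in NeOT and 2.04% in NS. TRBJ1-1 was used by 15.4% in NeOT, 14.3% in NS, 8.99% in OCDC and 8.16% in the T library. TRAJ18 was used by 0 of 49 clonotypes in the T library and by 8.16% in NS. The named segments numbered 22 for the T library against NS, 21 for NeOT against NS, 20 for NeOT against OCDC and 20 for NeOT against T, and all had overlapping intervals. TRAV9 was used by 4.08% in the T library and 8.64% in NeOT. Its intervals overlapped with that of NS, as did those of all 16 TRAV subgroups of the T library and all 17 of NeOT. The 4 comparisons of TRAV9 with saline use the same NS library and do not support one another.

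Between NooT and NeOT 4 of the 166 segments seen had intervals apart. When their clonotypes were dealt out at random to 2 sets of the same sizes, a check added after the values were seen, 1000 draws gave a mean of 1.15 and up to 8 such segments. In 29 draws there were 4 or more, so chance is not excluded for any single segment below. TRBV13-1 (GRCm38 chromosome 6, 41116036 to 41116468, a V segment) was used by 6.46% of NooT clonotypes (5.76% to 7.21%) and 1.85% of NeOT clonotypes (0.384% to 5.32%), higher in NooT with intervals apart. TRBV14 (chromosome 6, 41135167 to 41135616) was lower in NooT, at 1.51% (1.17% to 1.91%) against 5.56% in NeOT. Outside the named segments, and chosen after their values were seen, TRAV5-1 was used by 0.976% in NooT and 3.70% in NeOT, and TRAV9-2 by 1.22% and 4.94%, both with intervals apart. The intervals of the other 16 named segments overlapped, including TRBV3 at 9.74% and 7.41% and TRBJ2-7 at 18.6% and 14.8%. Of 18 TRBV families, TRBV14 alone had intervals apart. All 20 TRAV subgroups overlapped.

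**Figure D3:**
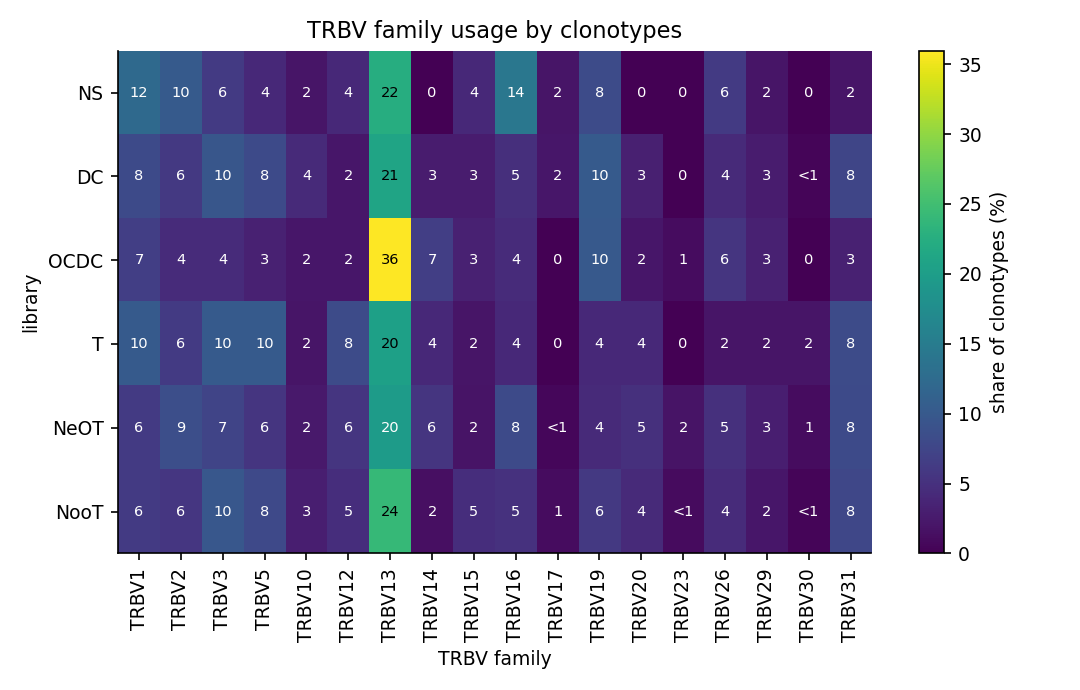
Heat map of the share of clonotypes (%, colour and printed values) that use each TRBV family (x axis) in each library (y axis). TRBV13, which includes the composite entry, was the most used family in every library, from 19.8% in NeOT to 36.0% in OCDC.

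The intervals of the TRBJ clusters and of the 2 parts of the TRAJ cluster overlapped in each of the 8 comparisons, which does not show that usage was equal. TRBJ2 segments made up 65.3% of NS clonotypes, 62.4% in DC, 71.9% in OCDC (61.4% to 80.9%), 71.4% in the T library, 58.0% in NeOT (50.0% to 65.7%) and 66.5% in NooT. TRAJ2 to TRAJ30 made up between 49.0% in NooT and 53.9% in OCDC. Counted by clonotypes, the median CDR3 length was 14 residues for TRA and for TRB in each of the 6 libraries, with an interquartile range of 13 to 15 for TRB. Counted by cells, the TRA median was 13 in NS, DC, NeOT and NooT and 14 in OCDC and the T library.

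Invariant NKT receptors, which recognise lipids on CD1d, were found in 5 of 93 OCDC cells (5.38%, 1.77% to 12.1%) and 2 of 51 NS cells (3.92%, 0.479% to 13.5%). DC had 1 of 225 (0.444%, 0.0113% to 2.45%), and NooT had 2 of 4896 (0.0409%, 0.00495% to 0.148%). NeOT had 0 of 188 and the T library 0 of 65, which allows up to 1.60% and 4.62%. OCDC and NS were higher than NooT with intervals apart. The exact interval of NeOT reached 1.94% and overlapped with that of OCDC, whereas its limit by 3 counts lay below it, so the order of these 2 libraries is not settled. The 5 OCDC cells were 5 different clonotypes, all with the TRA CDR3 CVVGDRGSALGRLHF and with TRBV29, TRBV13-3 or the composite entry as partner. TRAV11 lies on chromosome 14 at 53519303 to 53519859 and TRAJ18 at 54200777 to 54200842.

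**Figure D4:**
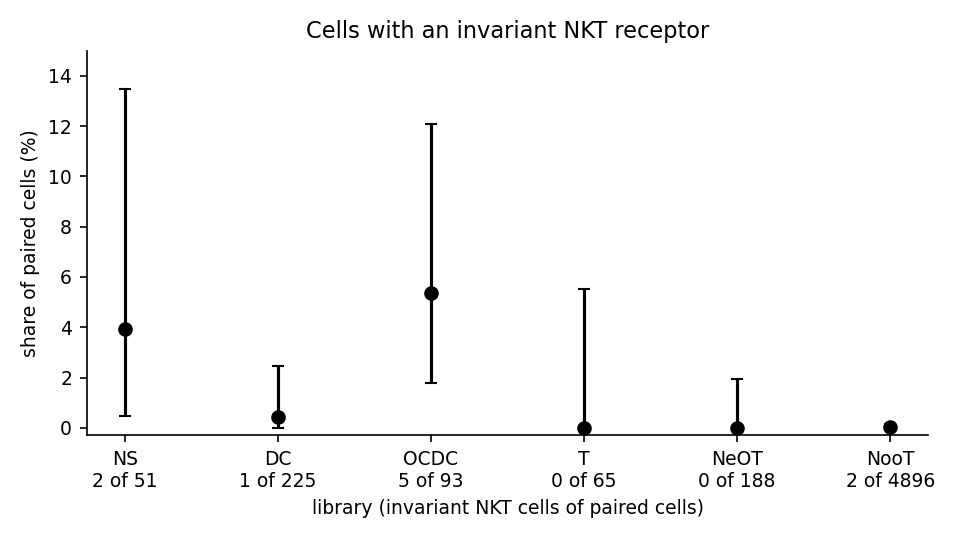
Share of paired cells with an invariant NKT receptor (%, y axis) per library (x axis, with counts). Points are shares and bars 95% exact binomial intervals. OCDC (5.38%) and NS (3.92%) had intervals above that of NooT (0.0409%).

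MAIT receptors, which recognise vitamin B metabolites on MR1, were found in 1 of 93 OCDC cells (1.08%) and in no paired cell of the other 5 libraries with a listed partner. TRG, TRD and immunoglobulin contigs were found in none of the called cells, which for the 7056 NooT cells allows a share of up to 0.0425%. An enrichment for TRA and TRB transcripts gives no measure of gamma-delta T cells or B cells.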

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

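The expanded shares at 51 cells and with 2 or more UMIs on both chains were planned, while their use here and every other test in this part were chosen after the results were seen. Productive TRA or TRB contigs outside called cells were a signal in data that the comparisons do not use. They were carried by 1.23% of such barcodes in NS (0.846% to 1.72%), 4.18% in DC, 3.06% in OCDC, 5.54% in NeOT, 10.6% in the T library (9.90% to 11.4%) and 66.2% in NooT. These shares give no ranking, because contigs with unrearranged TRBV26 were on 2602 of the 2691 barcodes in NS, 5615 of 6477 in the T library and 1 of 3321 in NooT. Among the barcodes without such a contig the share was 37.1% in NS (27.1% to 48.0%), 57.0% in DC (50.5% to 63.3%), 59.3% in OCDC (51.4% to 66.8%), 53.0% in NeOT (46.4% to 59.6%), 79.9% in the T library (77.1% to 82.6%) and 66.2% in NooT. The interval of NeOT then overlapped with that of NS, and those of the other libraries lay above it. In the T library they numbered 712 contigs with a median of 1 UMI and 227 distinct CDR3 sequences, and 25% of the contigs matched a called cell of that library. The TRB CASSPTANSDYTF was on 15 such barcodes and the TRA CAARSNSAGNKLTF on 7, and this pair is the receptor of 1 DC cell and 1 NooT cell. The TRA on all 7 had the bases of the DC cell and on 0 those of the NooT cell, whereas the TRB on all 15 had bases found in DC and also in NooT. Transfer of material between libraries is not excluded for this receptor. The largest DC clone was on 0 of these barcodes.

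The expanded share of the T library, the highest of the 6, was weighed against technical explanations. The number of cells sampled does not account for it, because the share expected at 51 cells was 37.0%, against 5.88% in NS. It also lay above the upper limit of 16.2% in NS, a limit that counts cells as independent. Barcode sequencing errors are argued against by the smallest difference between barcodes of 1 clonotype, 6 of 16 bases. With 2 or more UMIs on both chains the share was 41.1%, or 23 of 56 cells. That cut kept 56 of the 65 paired cells, so it is a weak check on free receptor RNA called as cells. Only 5.7% of the reads of the T library were in called cells, the lowest value of the 6 libraries. Capture of 2 barcodes in 1 droplet, which would count 1 cell as 2, stays open, as no value here tells 2 beads from 2 cells. In the T library 11 of 13 expanded clonotypes had exactly 2 cells, and in NeOT 16 of 20. The transfer itself, the biological difference that the label names, also stays open and untested, since 1 library stands for the group.

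Outside called cells the tumour libraries were dominated by contigs with TRBV26 (chromosome 6, 41227525 to 41227913) and no J or C segment, the unrearranged gene. They were on 94.7% of all listed barcodes in NS, 85.8% in DC, 91.8% in OCDC, 85.6% in the T library and 81.5% in NeOT, and on 1 barcode in NooT. Reads that escaped the V(D)J enrichment are a candidate source, since the median reads per UMI were at most 0.00181 of those of productive contigs in cells of the same library. Treatment of the mice is not needed for such contigs to arise, because saline had them on 2602 barcodes. The 94.7% in saline was the highest share, but a share also depends on how many other barcodes are listed. By number NS lay below DC (3081), OCDC (3063) and the T library (5615) and above NeOT (1974). An effect of treatment on their amount therefore stays open. Free RNA in every droplet cannot be told apart, because 0 of 728 called tumour cells carried such a contig but the number of all droplets is unknown.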

How the results depend on the processing

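Of 278 values recomputed for the reported comparisons under the alternatives, 262 stayed inside the 95% interval of the main value or within 1.5 times the main count. The alternatives reuse mostly the same cells and the intervals of small libraries are wide, so staying inside them is a weak check. The nucleotide CDR3s without V and J were chosen after seeing the data and moved none. DC and NeOT had a higher expanded share than NS and OCDC in all 12 settings, the main one included. The T library was highest in 11, the exception being clonotypes of 3 or more cells. Apart from the common number of 51 cells, the 12 settings compare libraries of unequal cell numbers. With 3 or more cells the share was 14.7% in DC, 10.8% in the T library, 7.45% in NeOT and 6.21% in NooT, lower by construction. It stayed at 6.45% in OCDC and 5.88% in NS, so NeOT lay close to both. At the common number of 51 cells the share was 12.0% in DC, 8.68% in NeOT and 0.318% in NooT, because fewer cells hold fewer repeats. With exactly 1 TRA and 1 TRB it was 20.4% in DC, whose largest clone holds cells with more than 1 TRA. In NooT it was 18.7% with the TRB chain alone, 11.7% with the deposited clonotypes and 11.7% with 2 or more UMIs on both chains, where the cause was not tested. The share of DC cells with a NooT receptor was 1.78% by amino acid CDR3s against 0% by nucleotides. It was 2.13% against 0.532% in NeOT and 2.15% against 0% in OCDC, and 0% by both in the T library and NS. Pairs of tumour libraries with a shared clonotype numbered 2 with the TRB chain alone and 2 with amino acid CDR3s against 0 in the main setting. Segments with intervals apart between NooT and NeOT numbered 7 when counted by cells and 2 with the TRB chain alone, which leaves out TRA segments, against 4. No paired analysis was possible because each group had 1 library. The 51 paired cells of NS limit every comparison with saline.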

Other observations

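All tests in this part except the random re-pairing for identical receptors were chosen after the results were seen. Tumour libraries given different treatments held families of near-identical receptors, defined as receptors of 2 libraries with the same V subgroups, J segments and lengths and at most 1 residue apart in each CDR3. There were 28 such pairs of receptors in 11 families, and 13 of the pairs joined tumour libraries to one another. TRAV6/TRAJ23 with TRBV1/TRBJ2-3 was found in DC, OCDC and the T library, with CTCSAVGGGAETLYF in each and a TRA that varied at 1 position (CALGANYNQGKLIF, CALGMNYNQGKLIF and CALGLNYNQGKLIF). TRAV13/TRAJ42 with TRBV31/TRBJ1-4 joined DC, OCDC, NeOT and NooT (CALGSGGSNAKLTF with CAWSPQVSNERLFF in DC and with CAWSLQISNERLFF in NeOT). TRAV7/TRAJ17 with TRBV26/TRBJ1-2 joined DC, OCDC and NooT through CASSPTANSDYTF and related sequences, but 3 of its 6 pairs differed by 1 base, so whether that family is shared stays open.

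Of 56 expanded clonotypes in the 5 tumour libraries, 4 belonged to such families, and so did 19 of 479 clonotypes of 1 cell. The leading NeOT clonotype (5 cells, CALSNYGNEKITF with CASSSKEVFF) had a counterpart in 2 cells of the T library (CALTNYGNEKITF with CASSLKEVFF), and the CDR3s differed by 5 bases. The DC receptor of 9 cells with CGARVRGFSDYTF, which counts as 2 of the 4 because its TRA had 2 nucleotide forms, had a counterpart in 1 cell of the T library with the same TRA residues and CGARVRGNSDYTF. Without any residue difference, 10 receptors were found in 2 or more libraries, 9 of them with a NooT member. The size of NooT alone would give most matches to it: 2383892 possible pairs join it to a tumour library, against 105238 between tumour libraries. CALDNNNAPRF with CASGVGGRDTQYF was in DC, NeOT and NooT, each with its own nucleotide sequence. Within NooT, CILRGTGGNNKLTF with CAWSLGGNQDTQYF was in 4 cells with 4 nucleotide forms and also in 1 OCDC cell.

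For these identical and near-identical receptors, chance meeting of common chains is argued against by random re-pairing of TRA and TRB within libraries, which gave at most 1 shared receptor in 1000 draws, and chance meeting of like chains by at most 1 near-identical pair in 100 draws. Cross-library contamination as the main source is argued against because 1 of 12 matches without residue difference had identical bases. Contamination with 1 base error is argued against for 8 of these 12 matches, which differed by 2 or more bases. Of the 28 near-identical pairs 25 did, which makes 33 of 40 comparisons. Near-identical pairs differ by at least 1 base by definition, and by at least 2 where both CDR3s differ, so their count is partly fixed in advance. For the other 7 of the 40 comparisons, at most 1 base apart, contamination stays open, although 0 barcodes carried the same CDR3 in 2 libraries. Random re-pairing keeps each chain's frequency but breaks any preference of V segments for one another, so that preference stays open. Receptor families shared among tumour libraries are a hypothesis that these data allow: near-identical receptors were 19.6 times as frequent per possible pair between tumour libraries as between tumour libraries and NooT, which may reflect common selection, and no antigen was tested.

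That ratio came from 13 of 105238 possible pairs between tumour libraries and 15 of 2383892 with NooT. Pairs of 1 family are not independent, and with any 1 family left out the ratio lay between 12.1 and 27.2, the latter without TRAV7/TRAJ17. NS had 0 such pairs, against 3.77 expected at the rate of the other 4 tumour libraries. The ratio covers near-identical receptors only. With identical residues, 1 receptor joined DC to NeOT and 1 joined the T library to NeOT. With NooT, 4 were shared by DC, 2 by OCDC and 4 by NeOT. NooT also differed in library quality: 89.6% of its reads were in called cells, against 5.7% in the T library to 23.4% in DC. Common selection cannot be told apart from such differences between libraries.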
